A study of Mus musculus with 13 samples.

How the data were processed

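Bulk RNA-seq of 13 libraries from mouse small intestine was analysed, in 6 groups taken from the titles and genotypes in the labels. Per the labels, polyA RNA was extracted from whole organoids or from intestinal stem cells (ISCs) isolated by flow cytometry, and libraries were made with a non-directional kit. The deposited values were gene-level read counts, 1 table per library with 24054 genes, a column for both strands together and a column for each strand. The tables had the layout of the gene counts written by the aligner STAR, and STAR (version not given), DESeq2 1.22.2 and the mouse build mm10 were named per the submitters' processing notes. The gene annotation behind the counts was not given in the sources used here. Which output the submitters used DESeq2 for was likewise not stated, and the deposited counts were whole numbers with different totals per library.

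The column for both strands was used for every library. The 4 summary lines of each table (unmapped, multimapping, no feature, ambiguous) were left out of library sizes and tests, and their shares were kept as library quality values. Of the 24054 genes, 4575 had no count in any library. Gene symbols were matched to GENCODE vM21 on GRCm38, the reference annotation of the same build, for 23666 genes (98.4%). Coordinates, transcript lengths and the share of each transcript's 31-base words that occur in a transcript of another gene were taken from that annotation. Genes over 20% on that share were treated as uncertain, since reads of near-identical genes can be split or discarded in counting.

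Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, and the alternatives also used DESeq2 1.42.0. Annotation and plots used Python 3.11.15. Genes with low counts were removed with filterByExpr by group (minimum count 10), library sizes were scaled by TMM, and groups were compared with the edgeR quasi-likelihood test. Adjusted p-values were Benjamini-Hochberg values over all genes of a fit, with a threshold of 0.05. The 6 organoid libraries formed 1 fit (14208 genes, biological coefficient of variation 0.217, 3 residual degrees of freedom). The 7 ISC libraries formed another (14577 genes, 0.402, 4 degrees of freedom), because whole organoids and sorted cells differ in their spread. The different effect of Apc loss between organoids and ileal ISCs was tested as an interaction term in 1 fit of all 13 libraries (15208 genes, 0.341, 7 degrees of freedom). Standard errors (SE) of log2 fold changes were derived from the quasi-likelihood F statistic. Levels are in CPM from TMM-scaled library sizes within the fit of the comparison, given as mean ± SD over the libraries of a group, and values per library in the plots and in the account of Apc and of Hoxb9 were scaled over all 13 libraries. Fitted fold changes used a prior count of 0.125.

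A fold against a group without a single count was given as a lower bound, computed against 3 counts over that group. Such a bound shrinks in proportion to the reads left when a library of that group is left out. A ratio against 1 to 3 counts was given with its exact 95% counting interval. Intervals and floors cover counting error only, because reads carried no molecular identifiers. Replicates were separate samples per the labels, with 2 libraries in each group and 3 in the duodenal group. No label states that they came from separate animals or cultures, so p-values measure the spread between these samples, which may be partly technical. Replicate pairs differed by more than sampling noise (chi-square per degree of freedom 18.9 to 1655), so no library counted as a copy of another.

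The comparisons were the pairs of groups within each material, the interaction, the correlation and overlap of effects between organoids and ileal ISCs, and the overlap of both organoid comparisons. Those share the WT organoids, so 30 simulated pairs of unchanged groups against the same controls were drawn. The simulated groups were centred on the mean of those controls, so they hold no error shared through them. Groups, tests, gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where an alternative is said to have been chosen later. Per comparison, the rule named Apc, Lgr5, Atoh1 and Axin2. It added the 8 largest rises and the 8 largest falls among genes with adjusted p under 0.05, mean log2 CPM of at least 3 and groups without overlap, leaving out predicted gene models, mitochondrial genes, antigen receptor segments and sex-linked genes. From each gene list with at least 3 called members it took the 3 with the smallest adjusted p. Genes from outside this rule are said to be so, and a few genes that the rule names are not reported here.

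The 23 gene lists were Wnt/beta-catenin targets, intestinal stem cell signature, fetal/regenerative epithelium, enterocyte, Paneth, goblet, enteroendocrine, tuft, cell cycle, ribosome biogenesis and Myc targets, Notch pathway, BMP targets and antagonists, duodenum-enriched, ileum-enriched, immune cells, stromal and endothelial cells, immediate early and dissociation stress, interferon response, MHC class II, unfolded protein response, cholesterol synthesis, peroxisome and fatty acid oxidation (PPAR targets), and glycolysis and hypoxia. Each was tested against all other genes with camera at a preset correlation of 0.01, adjusted over 161 tests (23 lists in 7 contrasts). Of the 102 lists called in a contrast, none kept its call when the correlation between genes was estimated from the residuals, and both adjusted p-values are given where a call is reported. Called members were counted over all genes tested and with p adjusted over the list alone. A further list of sex-linked genes served to check the libraries. By it, both ileal Sec-Cre libraries were male, both ileal WT libraries female, 1 of 3 duodenal libraries male, and the organoids male except ISC-Cre replicate 1.

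The steps were tested on simulated counts drawn from the real means and library sizes with 200 changed genes. For Sec-Cre against WT organoids (13911 genes tested), 56% of 2-fold and 95% of 4-fold changes were recovered, with 13 false calls. For Sec-Cre against WT ileal ISCs (14275 genes), 0% and 11% were recovered with 1 false call, and for duodenal ISCs against WT (14296 genes) 1% and 46% with 3 false calls. In the ISC comparisons changes of these sizes could therefore go unseen. Far fewer genes were changed in the simulation than were called against WT in the data, which makes the adjusted threshold stricter. The recovered shares therefore need not hold in the comparisons themselves.

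Alternatives were DESeq2's size factors in edgeR, no filter, the replicate number as a block, the DESeq2 Wald test, a fit of the compared groups alone, a fit of all 13 libraries, and leaving out each library in turn. For gene lists they were an estimated correlation and fry. Where a left-out library left 1 sample in a group, that sample was assumed to vary like the other groups. Voom with a weight per library, an offset removing each library's trend with transcript length, and second-strand counts for the duodenal libraries were chosen after seeing the data. The length offset was tested on simulated counts with a length trend, where it brought the rank correlation of fold change with length from -0.745 to -0.0201 and false calls from 1214 to 11. These counts had a smaller spread than the ISC libraries and a straight, stronger trend. Sec-Cre against WT ileal ISCs had a rank correlation of -0.376, so the drop in false calls may not carry over. Expression of single transcripts or exons was not analysed here, and neither were WT ISCs of the duodenum.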

Results

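Gene expression was measured by RNA-seq in 13 libraries from adult mouse small intestine, to ask how loss of Apc acts in different cells and settings. Apc scaffolds the complex that degrades beta-catenin, so its loss leaves Wnt signalling switched on. Mice labelled Apc-null carried floxed Apc and a tamoxifen-inducible Cre. The Cre was driven either by Atoh1, the transcription factor of the secretory lineage (Sec-Cre), or by Lgr5, the receptor that marks crypt-base ISCs (ISC-Cre). The titles of the ileal WT ISCs name the reporter Lgr5DTR-GFP. All groups, WT included, received 2 doses of 1 mg tamoxifen. Whole organoids, which are self-renewing epithelial cultures, were grown from crypts labelled as ileal, with a time point of 10 days. The sample labels count these days from induction to plating and the design text from plating to collection, so the age of the cultures is unclear. They formed 3 groups of 2 libraries: Sec-Cre Apc-null, ISC-Cre Apc-null and WT. Sorted ISCs also formed 3 groups. Sec-Cre Apc-null and WT ISCs came from the ileum at 21 days (2 libraries each), and ISC-Cre Apc-null ISCs came from the duodenum at 14 days (3 libraries). Regions follow the labels of single samples. The extraction protocol shared by all samples names the duodenum alone, so the region of the organoids and of the ISCs called ileal rests on the sample labels. Total gene counts per library were 13631423 to 22182702 in organoids, 11524335 and 45516228 in ileal Sec-Cre ISCs, 15573041 and 18609373 in ileal WT ISCs, and 21580486 to 27336750 in duodenal ISCs.

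The ISC libraries differed in quality as well as in group. In ileal Sec-Cre replicates 1 and 2, 57.0% and 35.8% of reads were unmapped, against 5.01% to 13.9% in ileal WT. Paneth cell genes took 35.0% of the counts of Sec-Cre replicate 1, 1.23% of those of replicate 2 and 2.61% in each WT library. The 10 most abundant genes held 51.0% and 8.28% of the counts of these Sec-Cre replicates. Rn45s, the ribosomal RNA precursor, took 10.4% and 2.05% of them against 0.519% and 0.573% in WT, and Lars2, a mitochondrial tRNA synthetase gene, 8.60% and 1.66% against 0.0668% and 0.0560%. Multimapping reads were 11.1% and 9.32%, against at most 5.76% in ileal WT. The 3 duodenal libraries were strand-specific, with 98.5% to 98.9% of gene reads on the second strand, whereas the other 10 libraries had 48.4% to 51.1%. The first principal component, which held 82.2% of the variance of organoids and 56.7% of that of ISCs, separated WT from Apc-null organoids and duodenal from ileal ISCs.

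Apc itself, on chromosome 18 (34220924 to 34322552, GRCm38), was read in every library. Its level was 179.8 and 198 CPM in Sec-Cre, 189.5 and 237 CPM in ISC-Cre, and 156 and 137 CPM in WT organoids. In ISCs it was 109.6 and 48.6 CPM in ileal Sec-Cre, 112 and 125 CPM in ileal WT, and 247, 172 and 454 CPM in duodenal ISC-Cre libraries. These counts cover the whole gene, and a floxed allele loses only part of it, so they do not check the labels. By the edgeR test, Apc differed in ISC-Cre against WT organoids (log2 fold change 0.51 ± 0.15 SE, adjusted p = 0.0316) and in duodenal against ileal Sec-Cre ISCs (1.88 ± 0.50, adjusted p = 0.018). The first call was lost without Sec-Cre replicate 1 (adjusted p = 0.061), Sec-Cre replicate 2 (0.059), ISC-Cre replicate 2 (0.161) or WT replicate 2 (0.103), and in fits of the compared groups alone (0.052) or of all 13 libraries (0.439). The other was lost without ileal Sec-Cre replicate 2 (0.091) and with the transcript length correction (0.076). In duodenal against WT ileal ISCs, Apc was at 1.26 ± 0.49 (adjusted p = 0.107), and called by DESeq2 (0.044), with library weights (0.006) and in a fit of all 13 libraries (0.037). In Sec-Cre against WT organoids it was at 0.35 ± 0.15 (adjusted p = 0.117).

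In organoids, the first comparison addressed Apc loss driven in the secretory lineage. Wnt targets rose and genes of differentiated cells fell in Sec-Cre Apc-null relative to WT organoids (n = 2 each). Axin2, a feedback inhibitor of Wnt signalling on chromosome 11 (108920349 to 108950783), rose from 352 ± 136 to 890.3 ± 27.3 CPM (log2 fold change 1.34 ± 0.24 SE, adjusted p = 0.00518). Wnt6, a secreted ligand (chromosome 1, 74771892 to 74785322), had no count in WT and 247 ± 2.92 CPM in Sec-Cre organoids, at least 2645-fold higher (adjusted p = 4.51e-05). Sis, the brush border enzyme sucrase-isomaltase (chromosome 3, 72888557 to 72967863), fell from 1788 ± 716 to 5.72 ± 0.57 CPM (log2 fold change -8.29 ± 0.36, adjusted p = 2.76e-05). Atoh1 fell from 47.0 ± 1.75 to 12.4 ± 0.34 CPM (log2 fold change -1.92 ± 0.19, adjusted p = 0.000422). Lgr5 was at 247 ± 14.4 CPM in WT and 224 ± 122 CPM in Sec-Cre organoids (-0.14 ± 0.34, adjusted p = 0.778), and its value was 0.34 without Sec-Cre replicate 1 and -0.84 with adjusted p = 0.039 without replicate 2. In all, 4685 of 14208 genes changed, 2367 higher and 2318 lower. This count was 2608 without Sec-Cre replicate 1 and 2721 without replicate 2.

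Of 34 measured Wnt/beta-catenin targets, 23 rose and 1 fell (24 and 1 adjusted over the list alone). By camera the list stood above other genes (adjusted p = 8.43e-09, and adjusted p = 0.204 with an estimated correlation). Among them Apcdd1, a membrane Wnt inhibitor, rose from 9.83 ± 1.99 to 228 ± 36.1 CPM, and Tnfrsf19, a receptor also known as Troy, from 9.71 ± 3.88 to 326 ± 33.7 CPM. The secreted Wnt inhibitor Wif1 had a ratio of 524 to WT (95% counting interval 145 to 4331), and Wnt10a was at least 588-fold higher at 54.9 ± 7.09 CPM. The stem cell signature went both ways, with 12 of 33 members higher and 8 lower (14 and 9 adjusted over the list alone, camera adjusted p = 0.344). The urea transporter gene Slc14a1 rose by 3.91 ± 0.20 on the log2 scale while the water channel gene Aqp4 fell by 4.65 ± 0.34. Of 31 genes of fetal and regenerative epithelium, 23 rose and 2 fell (26 and 2 adjusted over the list alone, camera adjusted p = 2.08e-10, adjusted p = 0.128 with an estimated correlation). They included the calcium-binding annexin Anxa1 (log2 fold change 6.14 ± 0.23) and the glycoprotein gene Msln (6.94 ± 0.18).

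**Figure D1:**
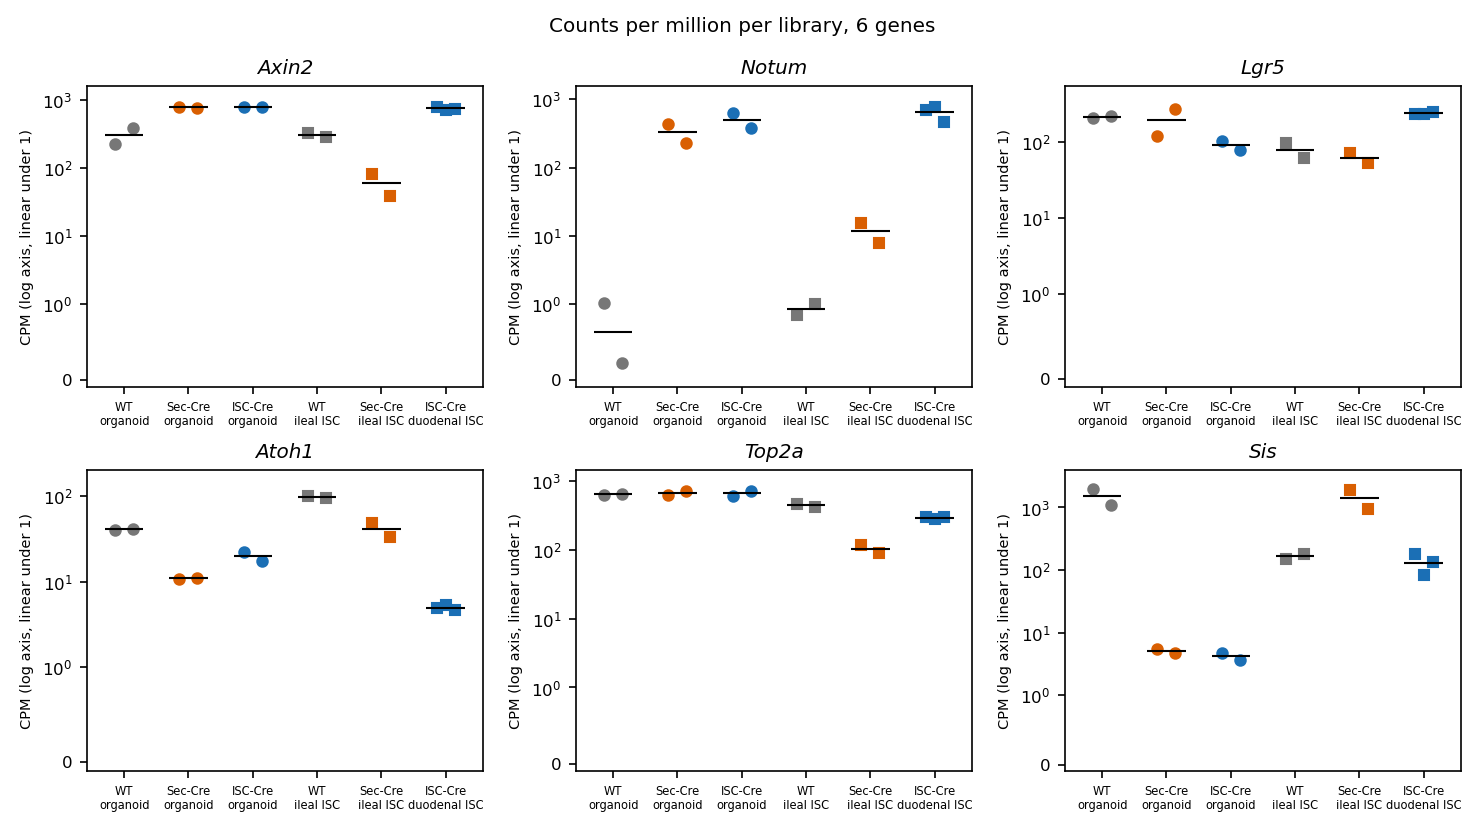
CPM of Axin2, Notum, Lgr5, Atoh1, Top2a and Sis in each of the 13 libraries, scaled over all libraries, with 1 point per library and a bar at the mean of each group (n = 2, or 3 for duodenal ISCs). The vertical axis is logarithmic and linear under 1 CPM. Axin2 lay at 764 to 797 CPM in Apc-null organoids, above the WT organoids at 221 and 388 CPM, and at 80.9 and 38.2 CPM in ileal Sec-Cre ISCs, below ileal WT at 325 and 286 CPM.

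Genes of differentiated cells fell together in Sec-Cre organoids. None of 35 enterocyte genes rose and 32 fell, also when adjusted over the list alone (camera adjusted p = 5.59e-17, adjusted p = 0.115 with an estimated correlation). Apoa1, an apolipoprotein of lipid export, fell from 315 ± 0.82 to 0.308 ± 0.304 CPM, and Mttp, which loads lipid onto lipoproteins, fell by 5.78 ± 0.25 on the log2 scale. Of 23 goblet genes 16 fell and none rose (17 adjusted over the list alone, camera adjusted p = 7.64e-10, adjusted p = 0.204 with an estimated correlation), among them the mucin gene Muc2, from 295 ± 8.96 to 8.48 ± 1.15 CPM. Of 30 enteroendocrine genes 21 fell and none rose (23 adjusted over the list alone, 1.79e-09, adjusted p = 0.246 with an estimated correlation). The hormone gene Sst had no count in Sec-Cre organoids and 42.1 ± 9.68 CPM in WT, at least 622-fold lower. Of 21 tuft genes 15 fell and 1 rose (16 and 1 adjusted over the list alone, 8.1e-07, adjusted p = 0.204 with an estimated correlation), including Rgs13, a regulator of G protein signalling (log2 fold change -3.93 ± 0.41). Of 22 Paneth genes 15 fell and 1 rose (17 and 1 adjusted over the list alone, 5.58e-08, adjusted p = 0.274 with an estimated correlation). The secreted phospholipase gene Pla2g2a fell from 2232 ± 119 to 248 ± 80.9 CPM, a call lost in a fit of all 13 libraries (0.273).

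Metabolic and regional genes also shifted in Sec-Cre organoids. Of 24 cholesterol synthesis genes 18 fell and none rose (19 adjusted over the list alone, camera adjusted p = 2.29e-09, adjusted p = 0.189 with an estimated correlation), with the lanosterol synthase gene Lss at -1.31 ± 0.15. Of 27 PPAR targets 21 fell and 1 rose (23 and 1 adjusted over the list alone, 1.15e-09, adjusted p = 0.169 with an estimated correlation), including the fatty acid oxidation gene Hadh, from 496 to 110.4 CPM (-2.17 ± 0.15). Of 24 glycolysis and hypoxia genes 13 fell and none rose (15 adjusted over the list alone, 7.03e-06, adjusted p = 0.529 with an estimated correlation), with the hypoxia-induced Ndrg1 at -2.95 ± 0.32. Duodenum-enriched genes fell in 15 of 22 cases (16 adjusted over the list alone, 1.79e-07, adjusted p = 0.169 with an estimated correlation). Of 27 ileum-enriched genes 20 fell and 1 rose (21 and 1 adjusted over the list alone, 1.48e-08, adjusted p = 0.17 with an estimated correlation). BMP targets and antagonists rose in 9 of 15 cases (10 adjusted over the list alone, 0.000389, adjusted p = 0.169 with an estimated correlation), among them Id3 at 3.35 ± 0.15 and Id1 at 1.82 ± 0.14, transcriptional inhibitors induced by BMP.

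Stress and cell-type marker lists were compared in the same organoids. Of 28 immediate early and dissociation stress genes 9 rose and 3 fell (10 and 3 adjusted over the list alone, camera adjusted p = 0.0112, adjusted p = 0.259 with an estimated correlation). Of 23 unfolded protein response genes 2 rose and 9 fell, with the same counts over the list alone (0.0149, adjusted p = 0.297 with an estimated correlation). The stress list lost its call without WT replicate 2 (0.126) and the unfolded protein response list without Sec-Cre replicate 2 (0.0545). Of 14 stromal and endothelial genes 6 rose and 1 fell (8 and 1 adjusted over the list alone, 0.00904, adjusted p = 0.204 with an estimated correlation). The intermediate filament gene Vim rose from 12.5 ± 1.43 to 478 ± 249 CPM and the basement membrane collagen gene Col4a1 from 0.248 to 107 ± 41.8 CPM. Cdh5, the cadherin of endothelial junctions, was at 12.7 ± 6.62 CPM with no count in WT, at least 136-fold higher. Camera called no shift of cell cycle genes (4 of 40 higher, adjusted p = 0.127). Adjusted over the list alone 0 of these were called by edgeR, with 13 at an unadjusted p under 0.05 and 8 called by DESeq2. Nor were ribosome biogenesis and Myc targets called (1 higher and 1 lower of 39, 0 and 1 adjusted over the list alone, 0.193), or Notch pathway genes (4 and 4 of 16, also adjusted over the list alone, 0.851). The same held for interferon response (5 and 6 of 31, 6 and 6 adjusted over the list alone, 0.789), MHC class II (1 and 1 of 6, also adjusted over the list alone, 0.905) and immune cell genes (2 of 5 higher, also adjusted over the list alone, 0.658).

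**Figure D2:**
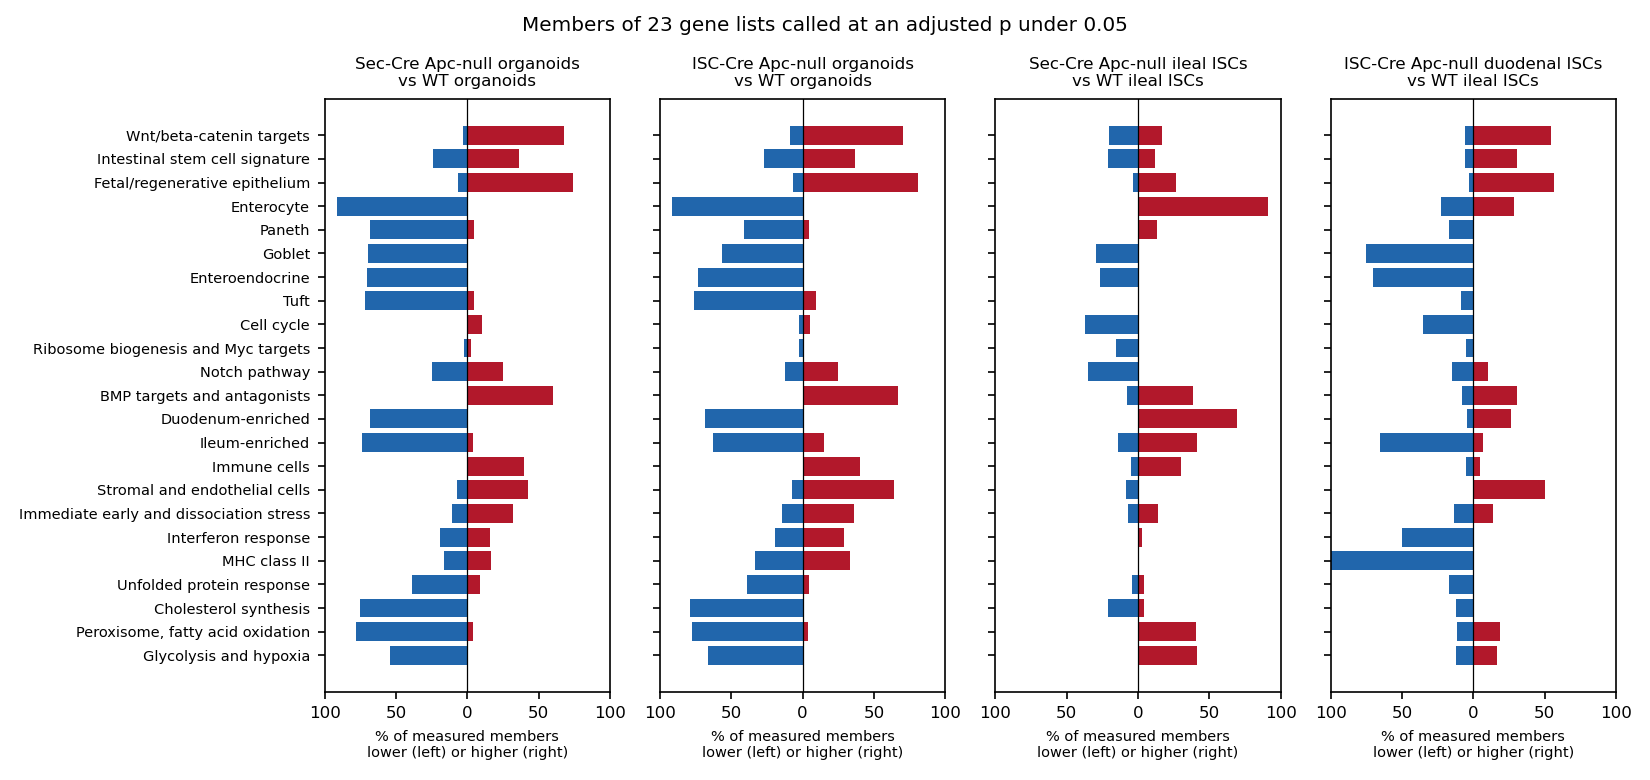
Percentage of the measured members of each of the 23 gene lists called lower (left of 0) or higher (right of 0) by the edgeR test in 4 comparisons. In Sec-Cre organoids 32 of 35 enterocyte genes were lower than in WT, and in Sec-Cre ileal ISCs 32 of 35 were higher.

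When Apc was lost through the ISC driver, organoids changed in the same lists. Axin2 rose from 352 ± 136 to 895 ± 9.98 CPM (log2 fold change 1.35 ± 0.24 SE, adjusted p = 0.00433, n = 2 each) and Wnt6 was at least 3264-fold higher than in WT, where it had no count. Sis fell to 4.73 ± 0.889 CPM (-8.56 ± 0.37) and Atoh1 from 47.0 ± 1.75 to 22.4 ± 3.78 CPM (-1.07 ± 0.19, adjusted p = 0.00383). Lgr5, into which the Cre of this genotype is knocked in, fell to 102 ± 19.9 CPM (-1.27 ± 0.34, adjusted p = 0.024). That call was lost without ISC-Cre replicate 1 (adjusted p = 0.078), ISC-Cre replicate 2 (0.151) or WT replicate 2 (0.063), and with library weights (0.068). In all, 5377 genes changed, 2749 higher and 2628 lower, and 3194 without ISC-Cre replicate 1 or 3400 without replicate 2.

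Of 34 Wnt targets 24 rose and 3 fell in ISC-Cre organoids (25 and 3 adjusted over the list alone, camera adjusted p = 4.34e-08, adjusted p = 0.204 with an estimated correlation), with Apcdd1 at a log2 fold change of 5.08 ± 0.21 and a Wif1 ratio of 1078 (95% counting interval 298 to 8903). The stem cell signature had 12 higher and 9 lower of 33 (13 and 10 adjusted over the list alone, adjusted p = 0.521), and Mex3a, an RNA-binding protein of slowly cycling ISCs, rose from 26.0 ± 2.14 to 147 ± 28.9 CPM. Fetal genes rose in 25 and fell in 2 of 31 cases (25 and 3 adjusted over the list alone, 4.89e-10, adjusted p = 0.128 with an estimated correlation), with Anxa1 at 6.31 ± 0.23. Enterocyte genes fell in 32 of 35 cases (32 and 1 higher adjusted over the list alone, 2.53e-15, adjusted p = 0.115 with an estimated correlation). Goblet genes fell in 13 of 23 (13 adjusted over the list alone, 2.98e-07, adjusted p = 0.259 with an estimated correlation), and enteroendocrine genes in 22 of 30 (23 adjusted over the list alone, 3.11e-08, adjusted p = 0.259 with an estimated correlation). Tuft genes fell in 16 and rose in 2 of 21 cases, also adjusted over the list alone (2.24e-05, adjusted p = 0.204 with an estimated correlation). Ptgs1, a prostaglandin synthase gene of that list, rose by 4.45 ± 0.52. Cholesterol synthesis genes fell in 19 of 24 (21 adjusted over the list alone, 1.69e-10, adjusted p = 0.17 with an estimated correlation), with Sqle, squalene epoxidase, at -1.25 ± 0.12. Paneth genes fell in 9 and rose in 1 of 22 (11 and 1 adjusted over the list alone, 0.00384, adjusted p = 0.534 with an estimated correlation).

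Both organoid effects ran in parallel across genes (Pearson r = 0.968, Spearman rho = 0.938 over 14208 genes, which are not independent replicates). Among called genes, 2173 rose in both comparisons and 2081 fell in both, against 458 and 429 for independent lists of the same sizes, and 3 went in opposite directions. Both comparisons use the same WT libraries. Simulated unchanged groups against them gave a mean r of 0.0558 and no shared call, and a covariance of 0.00747 against 5.09 observed. These groups were drawn around the mean of the same WT libraries, which leaves out the error shared through the controls. The simulation therefore cannot show how much of the agreement the shared controls bring. The 2 controls could not be split into parts of 2 each, so part of the excess may come from the shared controls.

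The direct comparison asked whether the driver of Apc loss left a difference between organoids. Of 14208 genes 6 were called, all lower in Sec-Cre than in ISC-Cre organoids (n = 2 each). Of these, 4 were HoxB genes, transcription factors that set position along the body axis, in 1 cluster on chromosome 11. Hoxb9 (96271457 to 96276595) was at 0.848 ± 0.34 against 111 ± 21.2 CPM (log2 fold change -7.01 ± 0.70 SE, adjusted p = 0.0347). Scaled over all libraries, it was at 1.84 and 8.07 CPM in WT organoids, nearer to Sec-Cre than to ISC-Cre organoids. Hoxb7 (96286623 to 96290162, -5.91 ± 0.46, adjusted p = 0.0196) and Hoxb6 (96292476 to 96301569, -4.79 ± 0.43, adjusted p = 0.0288) were also lower. Hoxb3 (-3.35 ± 0.32, adjusted p = 0.0288) is uncertain, since 69.5% of its 31-base words occur in another gene's transcript. The neighbours Hoxb8 (-6.21 ± 0.73, adjusted p = 0.0711) and Hoxb4 and Hoxb5 (adjusted p = 0.189 each), looked up after the others were seen, did not pass. Reg4, a lectin of secretory cells, was at 24.1 ± 0.462 against 116 ± 22.7 CPM (-2.27 ± 0.18, adjusted p = 0.0196). The Paneth lysozyme gene Lyz1 was at 706 ± 138 against 3238 ± 772 CPM (-2.20 ± 0.21, adjusted p = 0.0288), with 34.2% shared words. Without Sec-Cre replicate 1, Hoxb7 and Lyz1 kept their calls, and without ISC-Cre replicate 2 Reg4 did. Without Sec-Cre replicate 2 or ISC-Cre replicate 1 none of the 6 was called (adjusted p = 0.092 and 0.346 for Hoxb9), while all 6 were without either WT replicate.

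Axin2 (log2 fold change -0.01), Lgr5 (1.13, adjusted p = 0.984), Atoh1 (-0.85, adjusted p = 0.749, and 0.026 by DESeq2) and Apc (-0.17) were not called between Sec-Cre and ISC-Cre organoids. Apc was at 0.01 without ISC-Cre replicate 2, and Axin2 at 0.02 without Sec-Cre replicate 2 and 0.01 without ISC-Cre replicate 2. The count of called genes was 3 without Sec-Cre replicate 1, 0 without Sec-Cre replicate 2 (edgeR, 372 genes at an unadjusted p under 0.05), 0 without ISC-Cre replicate 1 (412 genes), 5 without ISC-Cre replicate 2 and 9 without either WT replicate. At an unadjusted p under 0.05 there were 719 genes in the full comparison, and DESeq2 called 72. Goblet genes stood lower as a list in Sec-Cre organoids (camera adjusted p = 1.54e-09, adjusted p = 0.207 with an estimated correlation), with 0 of 23 called by edgeR, 8 lower adjusted over the list alone, 10 at an unadjusted p under 0.05 and 7 by DESeq2. Paneth genes did too (2.23e-10, adjusted p = 0.259 with an estimated correlation), with 1 of 22 called, and 9 lower and 1 higher adjusted over the list alone. Wnt targets also stood lower (0.0092, adjusted p = 0.395 with an estimated correlation), a list call that depended on ISC-Cre replicate 1. By edgeR 0 of 34 were called, also adjusted over the list alone, 6 reached an unadjusted p under 0.05, and DESeq2 called 1. Ileum-enriched genes stood lower (0.00239, adjusted p = 0.259 with an estimated correlation), with 2 of 27 called, Hoxb7 and Hoxb6, and 3 lower adjusted over the list alone. Without the 3 HoxB genes of that list the other 24 had an unadjusted camera p of 0.234, a test chosen after the data were seen. Ribosome biogenesis genes stood higher (2.23e-10, adjusted p = 0.369 with an estimated correlation), as did cell cycle (3.69e-07, adjusted p = 0.338 with an estimated correlation) and cholesterol synthesis genes (2.06e-07, adjusted p = 0.204 with an estimated correlation). By edgeR 0 members of these lists were called, 5, 3 and 2 reached an unadjusted p under 0.05, and DESeq2 called 0.

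**Figure D3:**
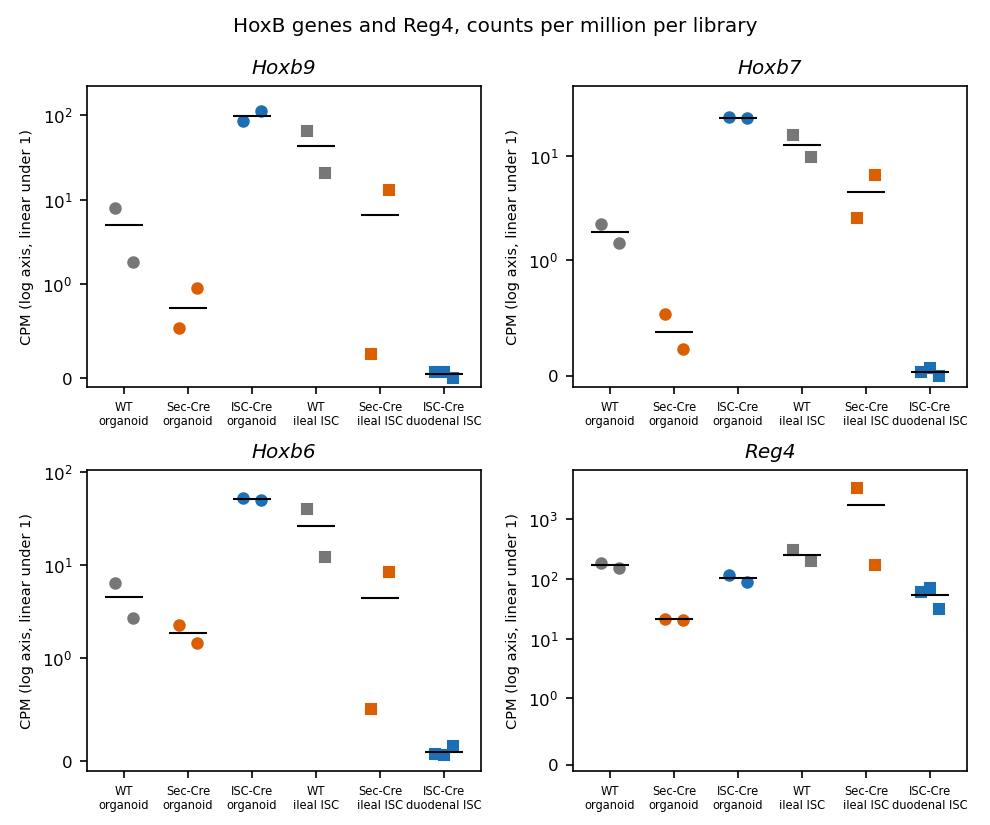
CPM of Hoxb9, Hoxb7, Hoxb6 and Reg4 in each of the 13 libraries, scaled over all libraries, with 1 point per library and a bar at the group mean on an axis that is logarithmic and linear under 1 CPM. Hoxb9 lay at 84.4 and 110.8 CPM in ISC-Cre organoids, at 0.532 and 0.956 CPM in Sec-Cre organoids, at 1.84 and 8.07 CPM in WT organoids, and at 20.6 and 65.7 CPM in ileal WT ISCs. It lay at 0.252 and 12.9 CPM in ileal Sec-Cre ISCs and at no more than 0.0667 CPM in duodenal ISCs.

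In sorted ISCs labelled ileal, the same Sec-Cre driver gave the contrast that the labels match for region, time and reporter. The Sec-Cre libraries were male and the WT libraries female, and the region rests on the labels alone. Enterocyte genes were higher and cell cycle genes lower in Apc-null than in WT ISCs (n = 2 each). Axin2 was at 53.0 ± 26.9 against 278 ± 25.4 CPM (log2 fold change -2.40 ± 0.41 SE, adjusted p = 0.00785), and Atoh1 at 36.4 ± 9.75 against 89.5 ± 3.8 CPM (-1.30 ± 0.31, adjusted p = 0.0246). Ace, the brush border angiotensin-converting enzyme, rose from 16.6 ± 2.11 to 592 ± 1.61 CPM (5.16 ± 0.40, adjusted p = 0.0013). Lgr5 was at 55.0 ± 11.8 against 71.9 ± 22.4 CPM (-0.39 ± 0.31, adjusted p = 0.414, and 0.09 with the length correction), and Apc at -0.62 ± 0.52 (adjusted p = 0.435). In all, 2417 of 14577 genes changed, 1403 higher and 1014 lower. The Axin2 call was lost without WT replicate 1 (adjusted p = 0.065) or 2 (0.060), and the Atoh1 call without WT replicate 1 (0.148), WT replicate 2 (0.14) or duodenal replicate 1 (0.054), and in a fit of the compared groups alone (0.055). The count of changed genes was 272 without WT replicate 1, 153 without WT replicate 2, and 1423 and 1512 without duodenal replicates 1 and 2, which share the fit.

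Of 35 enterocyte genes 32 rose in Sec-Cre ileal ISCs and none fell (33 and 0 adjusted over the list alone, camera adjusted p = 3.88e-23, adjusted p = 0.17 with an estimated correlation). Dgat2, an enzyme of triglyceride synthesis, rose from 23.9 to 228 ± 40 CPM. The glucose transporter gene Slc5a1 rose from 180.1 to 1894 CPM, a call lost without WT replicate 2 (adjusted p = 0.054). The enterocyte list took 2.32% and 3.47% of the counts of the Sec-Cre replicates and 0.458% and 0.438% of those of WT. Duodenum-enriched genes rose in 16 of 23 cases, 16 and 1 lower adjusted over the list alone (3.2e-08, adjusted p = 0.169 with an estimated correlation), with the alcohol dehydrogenase gene Adh6a at 533 against 5.96 CPM. Ileum-enriched genes stood higher as well, 12 higher and 4 lower of 29 (14 and 8 adjusted over the list alone, 0.0134, adjusted p = 0.276 with an estimated correlation). That call was lost without Sec-Cre replicate 2 (0.0502) or WT replicate 2 (0.0594) and with the length correction (0.103). Of 27 PPAR targets 11 rose (17 and 1 lower adjusted over the list alone, 3.45e-08, adjusted p = 0.204 with an estimated correlation). Creb3l3, a transcription factor of lipid metabolism, rose from 0.551 to 457 ± 127 CPM (log2 fold change 9.64 ± 0.87). Glycolysis and hypoxia genes rose in 10 of 24 cases (13 adjusted over the list alone, 0.000788, adjusted p = 0.351 with an estimated correlation). Otop3, a proton channel gene, had no count in WT and was at least 398-fold higher, and the alarmin gene Il33 rose by 5.65 ± 0.52 from 0.315 CPM.

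Of 40 cell cycle genes 15 fell and none rose in Sec-Cre ileal ISCs (21 lower adjusted over the list alone, camera adjusted p = 1.79e-09, adjusted p = 0.259 with an estimated correlation). Top2a, the topoisomerase of dividing cells, was at 93.0 ± 18.3 against 406 ± 38.5 CPM (log2 fold change -2.13 ± 0.30). Its call was lost without WT replicate 1 (adjusted p = 0.053) or 2 (0.052). Ribosome biogenesis genes fell in 6 of 39 cases (12 adjusted over the list alone, 0.000692, adjusted p = 0.479 with an estimated correlation), with the nucleolar gene Utp20 at 17.6 ± 1.35 against 89.3 ± 0.61 CPM. Wnt targets went both ways, 6 higher and 7 lower of 35 (9 and 12 adjusted over the list alone, adjusted p = 0.135). Lrp5, a Wnt co-receptor, fell by 2.75 ± 0.36, while the secreted Wnt deacylase gene Notum rose from 0.852 to 10.4 ± 4.67 CPM, with 34.1% shared words and a call lost without WT replicate 1 (0.053) or 2 (0.053). The stem cell signature stood lower, with 4 higher and 7 lower of 33 (4 and 10 adjusted over the list alone, 0.0137, adjusted p = 0.204 with an estimated correlation, and 0.167 with the length correction). Enteroendocrine genes fell in 8 of 30 cases (10 and 2 higher adjusted over the list alone, 1.18e-05, adjusted p = 0.207 with an estimated correlation). Insm1, their transcription factor, was at -3.51 ± 0.60, a call lost without WT replicate 1 (0.055) or 2 (0.068). Across genes, the log2 fold change fell with transcript length (Spearman rho = -0.376), from a median of 0.86 in the shortest of 5 equal groups of genes to -0.55 in the longest. With the length correction 1867 genes were called, 1465 of them shared with the 2417.

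Several other lists were called in ileal ISCs with a dependence on 1 library. Paneth genes stood higher (3 of 23 higher, 12 and 1 lower adjusted over the list alone, camera adjusted p = 0.0112, adjusted p = 0.663 with an estimated correlation) but lower without Sec-Cre replicate 1 (0.177). They were also not called without WT replicate 1 (0.0599) or with the length correction (0.118). Goblet genes stood lower, 7 of 24 in both counts including adjusted over the list alone (0.0176, adjusted p = 0.534 with an estimated correlation), and higher without Sec-Cre replicate 2 (0.801). Tuft genes stood higher (0.011, adjusted p = 0.677 with an estimated correlation) with 0 of 23 called by edgeR, by DESeq2 or at an unadjusted p under 0.05. They turned lower without Sec-Cre replicate 2 (0.584) and were not called without WT replicate 1 (0.924). Immune cell genes rose in 6 and fell in 1 of 20 cases (7 and 1 adjusted over the list alone, 0.0132, adjusted p = 0.313 with an estimated correlation), not called without Sec-Cre replicate 2 (0.155) or with the length correction (0.0711). Fetal genes rose in 8 and fell in 1 of 30 cases (13 and 2 adjusted over the list alone, 0.0337, adjusted p = 0.204 with an estimated correlation). That call was lost without Sec-Cre replicate 1 (0.0594), Sec-Cre replicate 2 (0.221) or WT replicate 1 (0.102), and with the length correction (0.249). Notch genes fell in 7 of 20 cases (8 adjusted over the list alone, 0.0366, adjusted p = 0.213 with an estimated correlation), lost without Sec-Cre replicate 2 (0.0751), WT replicate 1 (0.0665) or duodenal replicate 3 (0.0560).

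The difference of Sec-Cre Apc-null from WT in organoids and in ileal ISCs was set side by side, with no library in common. In ISCs sex and library quality differed between these groups as well, and time differed between the materials. The interaction terms therefore compare 2 contrasts of libraries and cannot be credited to Apc loss alone. Axin2, Prox1, a transcription factor of Wnt-driven intestinal tumours, and Tnfrsf19 had positive interaction terms, of 3.80 ± 0.51, 7.18 ± 0.56 and 5.81 ± 0.48 on the log2 scale (adjusted p = 0.000258, 1.05e-05 and 1.46e-05). Their log2 fold changes were 1.34, 5.49 and 5.04 in organoids and -2.40, -1.62 and -0.71 in ileal ISCs. Sis, Mttp and Creb3l3 responded in the other direction (-11.30 ± 0.72, -8.48 ± 0.53 and -16.91 ± 0.98). Of 15208 genes 4013 had a different effect, 2039 higher and 1974 lower in organoids, and 2513 or 2571 without organoid Sec-Cre replicate 1 or 2. With the length correction 1444 were higher and 2238 lower. Lgr5 (0.31 ± 0.49, adjusted p = 0.709), Atoh1 (-0.56 ± 0.35, adjusted p = 0.264) and Apc (1.03 ± 0.61, adjusted p = 0.243) were not called. Lgr5 was at -0.39 without organoid Sec-Cre replicate 2, -0.06 without ileal WT replicate 1 and -0.33 with the length correction. Without ileal Sec-Cre replicate 1 Apc was called (1.68, adjusted p = 0.048), and without replicate 2 Atoh1 (-0.90, adjusted p = 0.049).

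By list, 34 of 35 enterocyte genes had a lower effect in organoids, also adjusted over the list alone (camera adjusted p = 3.17e-28, adjusted p = 0.115 with an estimated correlation). Wnt targets had a higher effect in 20 of 35 cases (24 and 1 lower adjusted over the list alone, 4.06e-08, adjusted p = 0.115 with an estimated correlation), and cell cycle genes in 18 of 40 (23 adjusted over the list alone, 4.43e-08, adjusted p = 0.259 with an estimated correlation). Top2a was at 2.23 ± 0.34 (adjusted p = 0.000612). PPAR targets had a lower effect in 21 of 27 cases (23 adjusted over the list alone, 5.14e-13, adjusted p = 0.115 with an estimated correlation) and glycolysis genes in 16 of 24, also adjusted over the list alone (2.15e-07, adjusted p = 0.313 with an estimated correlation). Across 13708 genes tested in both, the effects had r = -0.0658 and rho = -0.116, with r = 0.0387 without ileal WT replicate 1 and -0.108 without ileal Sec-Cre replicate 2. Called genes rose in both in 173 cases against 210.1 for independent lists and fell in both in 132 against 167. A further 449 fell in organoids and rose in ISCs (219 for independent lists), and 182 did the reverse (160.2). The count of genes that rose in both was 32 and 12 without ileal WT replicates 1 and 2, and 103 and 101 without duodenal replicates 1 and 2. That of genes that fell in both was 9 and 6, and 63 and 77, in the same order, 69 and 76 without organoid Sec-Cre replicates 1 and 2, and 204 and 216 without ileal Sec-Cre replicates 1 and 2. In opposite directions there were 631, or 105 and 61 without ileal WT replicates 1 and 2, and 398 and 408 without organoid Sec-Cre replicates 1 and 2.

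**Figure D4:**
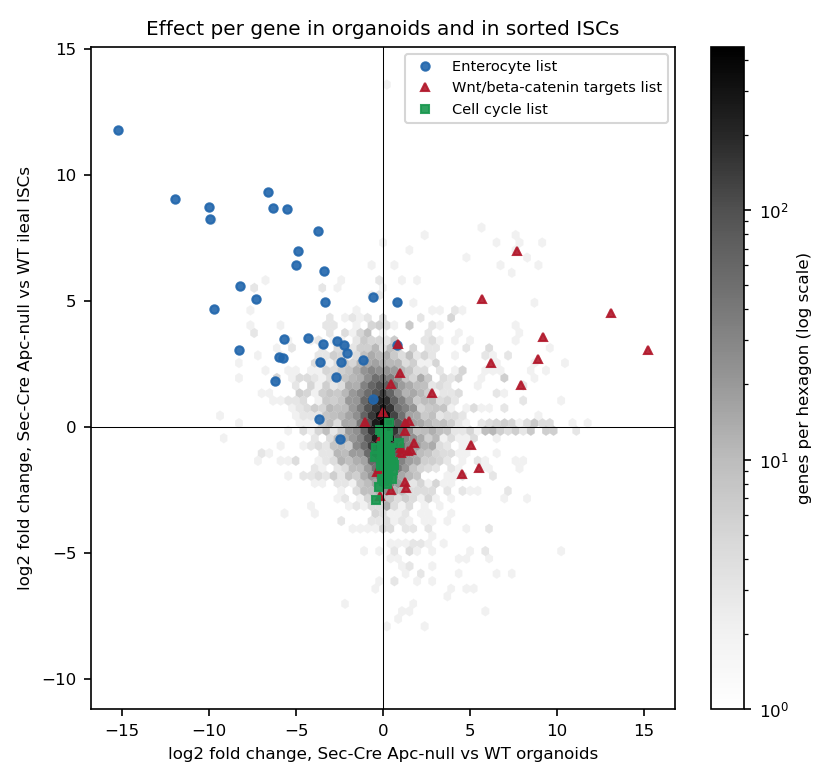
Log2 fold change of Sec-Cre Apc-null against WT in organoids (horizontal axis) and in ileal ISCs (vertical axis), with all 13708 genes as shaded hexagons and members of the enterocyte, Wnt target and cell cycle lists as points. Enterocyte genes lie at negative values in organoids and positive values in ISCs, and across all genes r was -0.0658.

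Apc-null ISCs from both drivers were compared directly. Driver, gut region, time, reporter and dissociation enzyme differ together between these groups, as do strand specificity and read mapping, so the contrast describes the libraries. Duodenal ISC-Cre ISCs (n = 3) had higher Wnt targets and lower differentiation genes than ileal Sec-Cre ISCs (n = 2). Axin2 was at 659.8 ± 41.1 against 53.0 ± 26.9 CPM (log2 fold change 3.65 ± 0.41 SE, adjusted p = 0.000454), Prox1 at 499 ± 129 against 3.3 CPM (7.34 ± 0.49) and Lgr5 at 211 ± 10.2 against 55.0 ± 11.8 CPM (1.94 ± 0.31, adjusted p = 0.00186). Atoh1 was at 4.38 ± 0.274 against 36.4 ± 9.75 CPM (-3.05 ± 0.28). The gastric mucin gene Muc5ac had no count in Sec-Cre ISCs and 119.8 ± 55.1 CPM in duodenal ISCs, at least 1949-fold higher. In all, 5950 genes differed, 3060 higher and 2890 lower. Of 35 Wnt targets 23 were higher and 1 lower (25 and 2 adjusted over the list alone, camera adjusted p = 9.35e-08, adjusted p = 0.128 with an estimated correlation). Of 35 enterocyte genes 33 were lower (34 adjusted over the list alone, 6.53e-18, adjusted p = 0.204 with an estimated correlation), with the lipid enzyme gene Dgat1 at -4.48 ± 0.39. All 7 measured MHC class II genes were lower, also adjusted over the list alone (4.84e-07, adjusted p = 0.259 with an estimated correlation). H2-Ab1, an antigen-presenting chain, was at 16.8 ± 12.6 against 1798 ± 342 CPM. Interferon response genes were lower in 21 and higher in 1 of 34 cases (25 and 2 adjusted over the list alone, 2.27e-06, adjusted p = 0.466 with an estimated correlation). The immunoproteasome gene Psmb9 was at -3.99 ± 0.31. Immune cell genes were lower in 8 and higher in 2 of 20 cases (9 and 2 adjusted over the list alone, 0.00796, adjusted p = 0.28 with an estimated correlation), a call lost without ileal Sec-Cre replicate 2 (0.0838) or with the length correction (0.0570).

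Duodenal ISC-Cre and ileal WT ISCs differ in Apc status, region, time, reporter and dissociation enzyme at once. Wnt targets were higher and goblet and enteroendocrine genes lower in duodenal Apc-null ISCs (n = 3) than in ileal WT ISCs (n = 2). Notum had a log2 fold change of 9.38 ± 0.56 SE with 34.1% shared words, and Igfbp4, a secreted binding protein of insulin-like growth factors, was at 639 against 96.8 CPM (2.72 ± 0.30). Atoh1 was at -4.35 ± 0.29 (adjusted p = 0.000204) and the hormone gene Sct at -3.92. Lgr5 was at 1.55 ± 0.30 (adjusted p = 0.00928), lost without WT replicate 2 (0.136). Axin2 was at 1.25 ± 0.37 (adjusted p = 0.0455), lost without WT replicate 1 (0.179), WT replicate 2 (0.296) or duodenal replicate 1 (0.116), 2 (0.093) or 3 (0.073), and with the length correction (0.056). In all, 2783 genes differed, 1494 higher and 1289 lower, with 1162 or 937 without WT replicate 1 or 2 and 1370 or 1452 without duodenal replicate 1 or 2.

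Of 35 Wnt targets 19 were higher and 2 lower in duodenal than in ileal WT ISCs (19 and 3 adjusted over the list alone, camera adjusted p = 1.53e-07, adjusted p = 0.128 with an estimated correlation). Fetal genes were higher in 17 and lower in 1 of 30 cases (21 and 1 adjusted over the list alone, 2.49e-08, adjusted p = 0.115 with an estimated correlation), among them Clu, which encodes clusterin, at 9.50 ± 0.80. Goblet genes were lower in 18 of 24 cases (19 adjusted over the list alone, 1.81e-13, adjusted p = 0.177 with an estimated correlation), including the granule lectin gene Zg16 at -5.13 ± 0.34. Enteroendocrine genes were lower in 21 of 30 cases (26 adjusted over the list alone, 1.5e-15, adjusted p = 0.128 with an estimated correlation), with the granule protein gene Chga at -4.45 ± 0.28. Paneth genes were not called as a list (adjusted p = 0.0559), with 4 of 23 lower (4 lower and 1 higher adjusted over the list alone). Tuft genes were lower in 2 of 23 cases (2 adjusted over the list alone, 0.0188, adjusted p = 0.712 with an estimated correlation), a list call lost without WT replicate 2 (0.837) and without duodenal replicate 2 (0.0763) or 3 (0.0894). Cell cycle genes were lower in 14 of 40 cases (22 adjusted over the list alone, 1.16e-09, adjusted p = 0.259 with an estimated correlation), with the mitotic gene Hmmr at 18.2 against 58.7 CPM (-1.69 ± 0.27). Ileum-enriched genes were lower in 19 and higher in 2 of 29 cases (20 and 3 adjusted over the list alone, 1.34e-09, adjusted p = 0.139 with an estimated correlation), with the bile acid binding protein gene Fabp6 at 0.167 against 231 CPM. Enterocyte genes went both ways, 10 higher and 8 lower of 35 (13 and 8 adjusted over the list alone, adjusted p = 0.706). Stromal and endothelial genes were higher in 6 of 12 cases (7 adjusted over the list alone, 0.00204, adjusted p = 0.169 with an estimated correlation). Cdh5 was at least 1084-fold higher, with no count in WT.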

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

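The tests of explanations in this part were chosen only after the results were seen, whereas the interaction terms were planned before the data were examined. The contrast of Sec-Cre Apc-null with WT differed between organoids and ileal ISCs by a test of the difference itself. In ileal ISCs sex and library quality differ together with Apc status, so this difference cannot be credited to Apc loss alone. Interaction terms passed the threshold for 4013 of 15208 genes, or 2513 and 2571 without organoid Sec-Cre replicates 1 and 2. The term was 3.80 on the log2 scale for Axin2. A higher effect in organoids was called for 20 Wnt targets and 18 cell cycle genes, and a lower one for 34 enterocyte genes.

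Read shares outside the gene counts stood apart from those of the controls in 5 libraries. Duodenal replicates 1, 2 and 3 had 98.9%, 98.8% and 98.5% of gene reads on the second strand, against 48.4% to 51.1% in the other 10 libraries. Their multimapping reads were 12.9%, 14.6% and 17.0% of the total, against 4.82% to 6.57% in organoids and ileal WT ISCs. Unmapped reads were 57.0% and 35.8% in ileal Sec-Cre replicates 1 and 2, against 5.01% to 13.9% in ileal WT.

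In Sec-Cre against WT ileal ISCs, 68 members of the Wnt target, stem cell, cell cycle and enterocyte lists were called, among them 15 cell cycle genes lower and 32 enterocyte genes higher. A gene that stands in more than 1 of these lists counts once in the totals and once in each of its lists. Without the Paneth-rich Sec-Cre replicate 1 most kept call and direction. They had been called with both replicates, so this is no independent test of that library. The whole enterocyte list took 3.47% of the counts of replicate 2 against 0.458% and 0.438% in WT, so its rise was also present there. With the transcript length correction 58 kept call and direction (32 of 32 enterocyte, 11 of 15 cell cycle, 7 of 11 stem cell and 10 of 13 Wnt genes). This argues against a length trend as the whole cause of these member calls. The call of the stem cell list was lost with the correction (camera adjusted p = 0.167), so a length trend stays open for that list. Dilution by cells without stem cell transcripts, as the whole cause of the lower Axin2 (-2.40), would lower the stem cell signature alike, but its median was -0.56 with a scaled median absolute deviation of 1.35, also with 1 gene set to its bound. Whether the added cells lack all these transcripts was not tested, and some members were called higher. Dilution by cells that hold part of the signature therefore stays open. Enterocytes among the sorted cells could bring the higher enterocyte genes and cannot be told apart from a change within ISCs. Lgr5 was at -0.39 without a call. The signature was called lower only before the length correction and at the preset correlation (camera adjusted p = 0.0137, adjusted p = 0.204 with an estimated correlation). Of the 35 enterocyte list genes, 29 exceeded 1 CPM in every WT library and 6 stood in another list. The abundant Apoa1 reached 18961 and 8266 CPM in Sec-Cre ISCs against 57.4 and 30.9 CPM in WT. A sort gated on the Lgr5 reporter is meant to remove enterocytes. It cannot be taken to have done so, since Paneth genes took 35.0% of the counts of Sec-Cre replicate 1. Sex (Sec-Cre male, WT female), the Cre itself, the unmapped reads and the share of sorted cells that had lost Apc stay open as untested. A difference in position along the gut was not tested either. Hoxb9 was at 0.252 and 12.9 CPM in Sec-Cre against 20.6 and 65.7 CPM in WT ISCs. Hoxb3 overlapped (1.26 and 1.62 against 1.53 and 15.3 CPM), and duodenum-enriched and ileum-enriched lists both stood higher in Sec-Cre ISCs.

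HoxB genes, Reg4 and Lyz1 were lower in Sec-Cre than in ISC-Cre organoids, with a median log2 fold change of -4.07 over the 6 genes. Hoxb9 in WT organoids was at 1.84 and 8.07 CPM. That is nearer to Sec-Cre (0.532 and 0.956 CPM) than to ISC-Cre organoids (84.4 and 110.8 CPM). Hoxb3 in WT, at 1.98 and 3.16 CPM, spanned Sec-Cre (2.79 and 2.82 CPM). Reg4 in WT, at 152 and 185 CPM, lay above both groups. Without the female ISC-Cre replicate 1 the median was -4.13, so the difference was also present with the male replicate 2 alone. The 6 genes had been called with both replicates, so this value was likely to stay large and is no independent test of that library. For crypts of ileum in one group and duodenum in the other, 8 other ileum-enriched genes, 6 of them lower, had a median of -0.37 ± 0.23 SE. Their median was -2.57 in duodenal Apc-null relative to ileal WT ISCs. There Apc status, time, reporter and enzyme differ along with region, and Cubn (2.30) and Tm4sf20 (0.06) were not lower. The 8 genes therefore cannot decide the question, although their shift was smaller than in that contrast. The 11 duodenum-enriched genes decide nothing either (0.23 ± 0.25, within its spread of the 0.45 there). The ileum list as a whole was called lower (camera adjusted p = 0.00239, adjusted p = 0.259 with an estimated correlation) but not without its 3 HoxB genes (24 genes, unadjusted camera p = 0.234). At most 1.21% of the 31-base words of Hoxb9, Hoxb7 and Hoxb6 occur in another gene, which argues against shared reads for these, while Hoxb3 (69.5%) and Lyz1 (34.2%) stay uncertain. A difference in position along the gut therefore stays open, and single regional genes went both ways. Gata4 was at 0.99 as it would predict (edgeR unadjusted p = 0.0200). Tm4sf20 at 0.58 and Cybrd1 at -1.45 went against it (unadjusted p = 0.0114 and 0.0406). The driver stays open as untested. Sex stays open because the comparison among male libraries rests on 1 ISC-Cre library and on genes called with both replicates.

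Vim, Cdh5 and Col4a1 were higher in the 7 Apc-null libraries of organoids and duodenal ISCs than in WT, whereas in ileal Sec-Cre ISCs Vim was at 1.76 and 2.48 CPM against 9.89 and 13.8 CPM in ileal WT. Endothelial cells are argued against by Pecam1, Kdr and Plvap, which reached at most 0.574, 0.076 and 1.1 CPM in these 7 libraries and at most 7.03% of Cdh5 in the same library, under a bound of 20%. Fibroblasts as the source of Vim at its level are argued against by their collagen and proteoglycan genes, at most 3.72% of Vim, with Col1a1 at up to 1.35 CPM in organoids and 20.2 CPM in duodenal replicate 2, but a smaller number of mesenchymal cells stays open, since Sparc and Pdgfra were called higher in both organoid groups and duodenal ISCs (Sparc at 9.34 ± 4.37 CPM in ISC-Cre organoids, Pdgfra at most 9.73 CPM), Dcn in both organoid groups (at most 0.879 CPM), Acta2, Tagln and Gsn in ISC-Cre organoids and Acta2 in duodenal ISCs, whereas Pdgfrb was called lower in both organoid groups (0.271 and 0.433 against 3.98 CPM in WT), calls that were not tested with libraries left out. Of the 23 stromal and endothelial list genes, 4 exceeded 1 CPM in every ileal WT library and 0 stood in another list. A gate on the Lgr5 reporter is meant to remove such cells from ISCs, whereas organoids were unsorted. Since Paneth genes took 35.0% of the counts of the sorted ileal Sec-Cre replicate 1, the gate cannot be taken to exclude other cells. Expression by the Apc-null epithelium itself is a candidate explanation that was found and tested on the same data, and for the duodenal ISCs region, time and dissociation stay open as untested.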

How the results depend on the processing

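The library weights (voom), the transcript length correction and the second-strand counts were chosen after the data were seen, and all other alternatives before. Counts of changed genes stayed within 1.5 times those reported with DESeq2's size factors, second-strand counts and the length correction, and without the low-count filter except in the direct organoid comparison. That comparison of Sec-Cre with ISC-Cre organoids, with 6 calls, gave 24 without the filter, 72 by DESeq2, 11 in a fit of the compared groups alone, 1 in a fit of all 13 libraries, 12 with library weights, and 0 to 9 without each library in turn. In the fit of all 13 libraries, which takes in the wider spread of the ISCs, calls against WT organoids fell to 2477 for Sec-Cre and 2997 for ISC-Cre, and calls against ileal WT ISCs rose to 4291 for Sec-Cre and 4426 for duodenal ISCs. Without each library in turn the same 4 counts ranged from 2608 to 5101, 3194 to 5542, 153 to 3183 and 937 to 3962, so that counts rose without some libraries and fell without others. Sec-Cre against WT ileal ISCs gave 3790 calls by DESeq2 and 1336 in a fit of the compared groups, duodenal against WT ISCs 7375 with library weights, and the interaction 2513 to 4929 without each library. The causes of these changes were not tested. For Sec-Cre effects in organoids and ileal ISCs, r was -0.108 to 0.0387 without each library. Genes higher in both numbered 320 by DESeq2 and 12 to 210 without each library, genes lower in both 255 and 6 to 216, and genes changed in opposite directions 1060 and 61 to 792. The overlap of both organoid comparisons was 4254 genes, against 887 for independent lists. It was 0 in simulated unchanged groups, which leave out the error shared through the controls. Values close to 0 changed sign. Lgr5 was at 0.093 with the length correction in ileal ISCs, at -0.33 with it in the interaction, at -0.39 to 0.79 there without each library, and at -0.84 to 0.34 in Sec-Cre against WT organoids. Between Sec-Cre and ISC-Cre organoids Apc was at -0.32 to 0.0071 without each library, and Axin2 at 0.0049 without the filter, 0.0103 in the fit of all 13 libraries and -0.0359 to 0.0183 without each library. The length correction moved the share of higher calls from 58.0% to 66.4% in Sec-Cre against WT ileal ISCs (1867 calls, 1465 of them shared) and from 50.8% to 39.2% in the interaction, where the median of all genes moved from 0.16 to -0.06. Of 102 called gene lists, 102 lost the call with an estimated correlation and 26 by fry, and 9 of 62 with the length correction. Leaving out a library ended 36 of 752 list calls and turned 4. Glycolysis genes between Sec-Cre and ISC-Cre organoids turned without ISC-Cre replicate 1 (adjusted p = 0.947, range over all alternatives 9.79e-11 to 0.947). In ileal Sec-Cre against WT ISCs, Paneth genes turned without the Paneth-rich Sec-Cre replicate 1 (0.177, 3.16e-17 to 0.663), and goblet (0.801, 6.44e-06 to 0.801, and 9.62e-06 without replicate 1) and tuft genes (0.584, 1.52e-07 to 0.924) without replicate 2. Except for Paneth genes the cause was not tested. Of 421 named gene values, DESeq2 changed 2 calls, both gained, and leaving out a library ended 232 of 2930. Of named genes called, 72 of 75 kept the call without each library in Sec-Cre against WT organoids, 73 of 80 in ISC-Cre against WT organoids and 19 of 68 in Sec-Cre against WT ileal ISCs. The replicate numbers do not pair the libraries (correlations of deviations -0.0976 to 0.0731). With the number as a block, calls in duodenal against WT ISCs were 1671 instead of 2783, the other counts stayed within 1.5 times, and Notch genes in ileal Sec-Cre ISCs and cholesterol genes in duodenal against WT ISCs lost their list calls. Depth was at least 11524335 counts per library, and the spread between ISC libraries limits what can be seen, as 11% of simulated 4-fold changes were recovered in Sec-Cre against WT ileal ISCs.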

Other observations

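The values here come from comparisons fixed before the data were examined, except for the overlap below, whose test was chosen only after the result was seen. The contrasts of ISC-Cre with WT organoids and of duodenal ISC-Cre with ileal WT ISCs share no library. They ran in the same direction across 13708 genes (r = 0.652, rho = 0.558, genes not being independent replicates). Without each library in turn r was between 0.595 and 0.654. In the ISC contrast region, time, reporter and dissociation enzyme differ along with Apc status. The agreement and the values below therefore cannot be credited to Apc loss alone. Called genes rose in both in 911 cases and fell in both in 782, against 251 and 234 for independent lists, and 96 went in opposite directions. These 3 counts were 445, 363 and 34 without ileal WT replicate 1, 344, 357 and 28 without ileal WT replicate 2, 500, 483 and 47 without duodenal replicate 1, and 543, 477 and 52 without duodenal replicate 2. The opposite count was also 54 and 59 without ISC-Cre organoid replicates 1 and 2, and 148 and 151 without ileal Sec-Cre replicates 1 and 2. Robo1, an axon guidance receptor, had no count in either WT group and was at least 2128-fold higher in ISC-Cre organoids (198.9 ± 83.5 CPM, edgeR adjusted p = 7.58e-05) and at least 2084-fold higher in duodenal ISCs (157.8 ± 48.8 CPM, adjusted p = 0.000398). Cdh13, a cadherin without a membrane-spanning part, was at least 997-fold and 758-fold higher. Pdk4, a kinase that restrains glucose oxidation, rose by 5.77 ± 0.45 and 5.29 ± 0.77 on the log2 scale, and Anxa1 by 6.31 ± 0.23 and 6.24 ± 0.63. The lipid transcription factor gene Creb3l3 fell by 7.03 ± 0.39 in organoids and was 5.05 ± 0.72 higher in duodenal ISCs.

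Genes of antigen presentation were lower in duodenal Apc-null than in ileal WT ISCs. All 7 measured MHC class II genes were lower, also adjusted over the list alone (camera adjusted p = 3.2e-08, adjusted p = 0.242 with an estimated correlation). Ciita, the activator of this gene class, was at 2.24 ± 0.90 against 48.1 ± 11.5 CPM, and H2-Ab1 at 16.8 ± 12.6 against 398.5 ± 64.6 CPM. Interferon response genes were lower in 17 of 34 cases (18 adjusted over the list alone, 9.54e-06, adjusted p = 0.479 with an estimated correlation), with the immunoproteasome gene Psmb8 at -2.52 ± 0.31, and unfolded protein response genes in 4 of 23 (7 adjusted over the list alone, 0.000145, adjusted p = 0.251 with an estimated correlation). In the same comparison the gastric gland mucin gene Muc6 was at 901 ± 939 CPM with 1 count in WT (ratio 30477, 95% counting interval 5470 to 1203780). Replicate 3 carried most of that mean, at 2222 CPM scaled over all libraries against 415 and 402 CPM in replicates 1 and 2, and the log2 fold change of 14.86 was 13.54 without it, with the call kept. Onecut2, a duodenal transcription factor, was at 7.04 ± 0.80. Dll1, a Notch ligand of secretory progenitors, was at 10.8 ± 1.36 against 100.4 ± 0.62 CPM. In ISC-Cre organoids relative to WT, glycolysis and hypoxia genes fell in 16 of 24 cases (19 adjusted over the list alone, 2.98e-07, adjusted p = 0.473 with an estimated correlation) and PPAR targets in 21 of 27, with 1 higher (23 and 1 adjusted over the list alone, 7.76e-09, adjusted p = 0.169 with an estimated correlation). BMP targets and antagonists rose in 10 of 15 cases (12 adjusted over the list alone, 0.000145, adjusted p = 0.169 with an estimated correlation). MHC class II genes went both ways there, 2 higher and 2 lower of 6, also adjusted over the list alone (camera adjusted p = 0.583).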
